A study of Mus musculus with 12 samples.

How the data were processed

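RNA of mouse aortic arches was measured on 12 two-colour microarrays, 3 for each of 4 groups. The groups were Apoe-/- mice after 8, 16 or 24 weeks on a high-fat diet and wild type C57BL/6 mice after 16 weeks, per the labels. Each array held RNA pooled from 3 mice of a group, except pool 2 of the 8-week group, which held RNA of 2 mice. Per the labels, the pool carried the Cy5 dye on every array and a common reference carried Cy3. The reference was Apoe-/- aortic arch RNA mixed in equal amounts from the 3 diet times and labelled as RNA of 21 mice. No dyes were swapped, so a dye effect that is the same on all arrays drops out of a difference between groups but stays in the ratio of any single array. Per the labels' protocols, total RNA was purified on RNeasy columns with DNase treatment and amplified and labelled with an automated aminoallyl procedure. The labels place the tissue in the aortic arch, while the whole aorta was collected at dissection, and they mark pools 3 and 6 with an asterisk whose meaning is not given in the sources used here.

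The values analysed were the log10 ratios the authors deposited, 1 per probe and array, for 39556 probes. The scanner, the image analysis, the normalization and any filter are not given in the sources used here, and the log base and the direction of the ratio were settled from the values. For the direction, Apoe lay above the reference on all 3 wild type arrays and near it on all 9 Apoe-/- arrays, as a ratio of pool over reference gives for an Apoe-/- reference. For the base, transcripts found in a single pool were used. Pth in pool 10 had a value of 0.777 against a median of -1.16 in the 8 other Apoe-/- pools, which in base 10 needs that pool to make up 15.7% of the reference, but 43.6% in base 2 and 36.8% in base e. The same calculation for Prm1 in pool 1 gave 13.5%, 35.6% and 30.3%. For Jchain in pool 4 it gave 8.5%, 29.3% and 23.9%. A reference mixed in equal amounts from 3 times leaves little room for the larger shares in a single pool, so base 10 was used and the values were multiplied by 3.322 to give log2 ratios. The medians of the columns as deposited were 0.0109, 0.0174 and 0.0130 in wild type pools 16, 17 and 18. They were 0.0043, 0.0181 and 0.0071 in pools 1, 2 and 3 at 8 weeks, 0.0064, 0.0058 and 0.0019 in pools 4, 5 and 6 at 16 weeks, and 0.0005, -0.0012 and -0.0025 in pools 10, 11 and 12 at 24 weeks. Each array was therefore centred close to 0 by the authors' unstated processing, and the genes were not centred across arrays. The method of centring stays unknown. Ratios appear to have been limited at the low end, since Skint7 and Vmn1r38 shared the lowest value, -2.0 in pool 2 (-6.644 on the log2 scale). The rule for such a limit is not given in the sources used here. The values hold ratios and no intensities, so neither the level of a gene nor whether it lay above background on an array is known, and a fold against a group near the background can be too small.

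The arrays of the 24-week group correlated negatively across probes with those of the 8-week group (median r = -0.538), of the 16-week group (median r = -0.329) and of the wild type group (median r = -0.431). Such values can arise because the reference holds all 3 times and lies between them, and the labels state the dyes, so the direction was kept. Within groups the median r was 0.795 among wild type pools, 0.558 at 8 weeks, 0.409 at 16 weeks and 0.414 at 24 weeks. The probe annotation gave 1 gene symbol to 23283 probes and several to 0 probes, and 16273 probes carried no name. Symbols were updated through a mouse gene table of assembly GRCm38.p6: 14510 of 20551 symbols were current, 5952 were older names that were replaced, 78 were older names of several genes and were kept, and 11 were not found and were kept. The table also gave the order of genes along a chromosome, and its coordinates were not used. The probes of a gene were averaged, which gave 19896 genes, 2869 of them with 2 or more probes, and the 19705 genes with a value on every array were tested. No 2 arrays held identical values.

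Differences between groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 2.95 prior degrees of freedom) on the log2 ratios as deposited, with 1 mean per group over all 12 arrays. All p-values are two-sided unless stated, and adjusted p-values are those of Benjamini and Hochberg over the genes tested, with a threshold of 0.05. The 7 comparisons were the 3 Apoe-/- groups against wild type, the mean of the 3 against wild type, and the 3 pairs of diet times, with a moderated F test over the 3 times. Fold changes carry 95% confidence intervals from the same fit. A total of 39 gene lists (pathways and cell type markers) were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Camera with a correlation estimated per list and fry were alternatives. Fry tests whether the genes of a list move, on balance, in a single direction, and does not set them against other genes. Of 889 list members, 826 were on the array under their name. The groups, the comparisons, the gene lists, the alternatives and the rule for the genes named were chosen before the data were examined, apart from 2 alternatives given as added later.

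The rule named Apoe, then the 10 largest rises and the 10 largest falls at 16 weeks against wild type, and 5 of each in the other comparisons. These were taken from genes past the threshold whose pools did not overlap between the groups, and skipped clone and predicted names. It also named up to 4 members of each list that passed, with the smallest adjusted p, together with members that moved the other way, and the 10 genes with the smallest adjusted p in the F test. Genes outside the rule are marked in the text. The rule set no limit on how far the probes of a gene may differ, and each probe was fitted alone after the genes were named. Among the genes in the text, probes differed by more than 1 in log2 change for Zfp420 (2.97), Cd44 (1.57), Col8a1 (2.14) and Spp1 (1.27) at 16 weeks against wild type. At 24 weeks against wild type they did so for Col8a1 (2.12), Spp1 (1.80), Calm3 (1.21) and Kcnn4 (2.69), for 24 against 16 weeks for Tcf7l2 (2.10), and for 24 against 8 weeks for Col8a1 (1.01), Calm3 (1.44) and Kcnn4 (1.39). On simulated ratios of 19705 genes with the measured spread, the step recovered 65.7%, 94.0% and 100% of genes changed 1.5-fold, 2-fold and 4-fold between the 16-week and the wild type group, and 4.3% of its calls were false. For 16 against 8 weeks it recovered 64.2%, 92.5% and 98.5%, with 7.4% of calls false, and for the F test 59.7%, 94.0% and 100%, with 6.7% false. Each share rests on 66 or 67 simulated genes in a single draw, and an earlier draw gave shares that differed by several points. The simulated genes were independent and had the same spread on every array. The real arrays differed, with estimated weights from 0.15 in pool 2 to 2.7 in pool 4, so these shares may not hold for them. Alternatives were median-centred arrays, quantile normalization, single probes, the most variable probe per gene, genes with at least 2 values per group, dropping the 25% of genes with the lowest SD, fitting only the groups compared, robust eBayes, array weights, weights by mice per pool, leaving out pools 3 and 6, a minimum fold of 1.2 (limma's treat), wild type arrays against the reference alone, and leaving out each pool in turn. The tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.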

Results

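The arrays compared the aortic arches of mice lacking apolipoprotein E, which develop atherosclerosis on a high-fat diet, with those of wild type mice, and followed the Apoe-/- arch over 3 lengths of diet. All mice began the diet at 8 weeks of age, so age rose with the length of diet. Comparisons between diet times cannot tell age from length of diet. There were 3 pools per group, numbered 1 to 3 at 8 weeks, 4 to 6 at 16 weeks, 10 to 12 at 24 weeks and 16 to 18 for wild type. The pools held different mice, so the p-values measure the spread between pools of mice, and the small number of arrays limits the precision. Changes are log2 differences between groups of 3 pools, given with the standard error from limma, and folds are given with a 95% confidence interval. On the first principal component, with 55.2% of the variance, the wild type pools scored 28.3 to 38.4, the 8-week pools 7.3 to 31.9, the 16-week pools -18.8 to -5.5 and the 24-week pools -46.3 to -38.2. Pool 2 at 8 weeks had the widest ratios of all arrays (interquartile range 0.466 on the log2 scale, against 0.118 in pool 10). The mean of the 3 Apoe-/- group means lay within 2-fold of the reference for all but 26 of 19705 genes (SD 0.128), while the wild type mean lay beyond it for 703 genes (SD 0.461).

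Apoe itself separated the genotypes in every pool. Its log2 ratio to the Apoe-/- reference was 2.62, 2.01 and 2.85 in wild type pools 16, 17 and 18, and lay between -0.20 and 0.23 in the 9 Apoe-/- pools. Against wild type, Apoe was 5.90-fold lower at 16 weeks (confidence interval 4.55 to 7.65, adjusted p = 1.06e-05), 6.24-fold lower at 8 weeks (adjusted p = 5.59e-05) and 5.28-fold lower at 24 weeks (adjusted p = 2.59e-06). Apoe had 1 probe, and whether it lies in the deleted part of the gene is not given in the sources used here.

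At 16 weeks of diet, the time at which both genotypes were studied, genes of macrophages and of lipid-laden foam cells rose most in the Apoe-/- arch. The largest rise was that of Bex1, 38.6-fold (5.27 ± 0.34, n = 3 pools per group, confidence interval 22.8 to 65.4, adjusted p = 1.03e-05). Mmp12, the macrophage elastase, rose 28.2-fold (4.82 ± 0.34) and Atp6v0d2, a subunit of the vacuolar proton pump, 28.1-fold (4.81 ± 0.28). Il1rn, the interleukin-1 receptor antagonist, rose 22.7-fold, Mpeg1, a pore-forming protein of macrophages, 22.2-fold, Bcl2a1b 21.6-fold, and Ctss, the lysosomal protease cathepsin S, 20.4-fold. Trem2 and Lilrb4a, receptors of myeloid cells, rose 19.7-fold each, and Cd300c2 19.2-fold. The adjusted p of these 10 genes was at most 2.12e-05.

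The leukocyte lists rose together at 16 weeks. Of 30 macrophage genes, 21 rose and 9 did not pass (24 rose when adjusted over the list alone), with a mean of 1.81 ± 0.14 (camera adjusted p = 1.75e-29, and adjusted p = 0.0473 with an estimated correlation). Itgax rose 16.3-fold, Lgals3 6.95-fold and Fcgr3 6.73-fold. Of 24 foam cell genes, 20 rose and 4 did not pass (21 adjusted over the list alone), with a mean of 2.19 ± 0.17 (camera adjusted p = 1.75e-29, and adjusted p = 0.0524 with an estimated correlation). Among them Abcg1, a cholesterol exporter, rose 17.5-fold and Gpnmb 15.1-fold. Of 27 lysosomal genes, 18 rose (21 adjusted over the list alone), including Npc2, a lysosomal cholesterol carrier, 2.92-fold, Ctsz 2.61-fold and Hexa 2.01-fold. Their mean was 0.80 ± 0.10 (camera adjusted p = 2.19e-16, and adjusted p = 0.0787 with an estimated correlation). Of 30 chemokines and cytokines, 17 rose (19 adjusted over the list alone), including the chemokines Ccl3 5.39-fold, Ccl2 5.07-fold and Ccl6 4.51-fold. Their mean was 1.13 ± 0.16 (camera adjusted p = 4.34e-12, and adjusted p = 0.0787 with an estimated correlation). Of 13 genes of endothelial activation and adhesion, called endothelial activation below, 7 rose (9 adjusted over the list alone). They included the adhesion molecules Vcam1 6.52-fold, Cd44 1.85-fold and Icam1 1.79-fold. The list also holds Itgal, Itga4, Selplg and Cd44, which leukocytes express, so its rise need not come from endothelial cells. Only 1 of the 2 probes of Cd44 passed. The mean of the list was 0.81 ± 0.08 (camera adjusted p = 2.38e-08, and adjusted p = 0.0473 with an estimated correlation). Of 15 genes of MHC class II presentation, 9 rose (11 adjusted over the list alone), with H2-Eb1 6.79-fold and Cd86 3.76-fold higher. Their mean was 1.06 ± 0.12 (camera adjusted p = 6.81e-11, and adjusted p = 0.0538 with an estimated correlation). Ctss stood in the lysosomal, the MHC class II and the protease list, and the lists overlap in this way throughout.

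**Figure D1:**
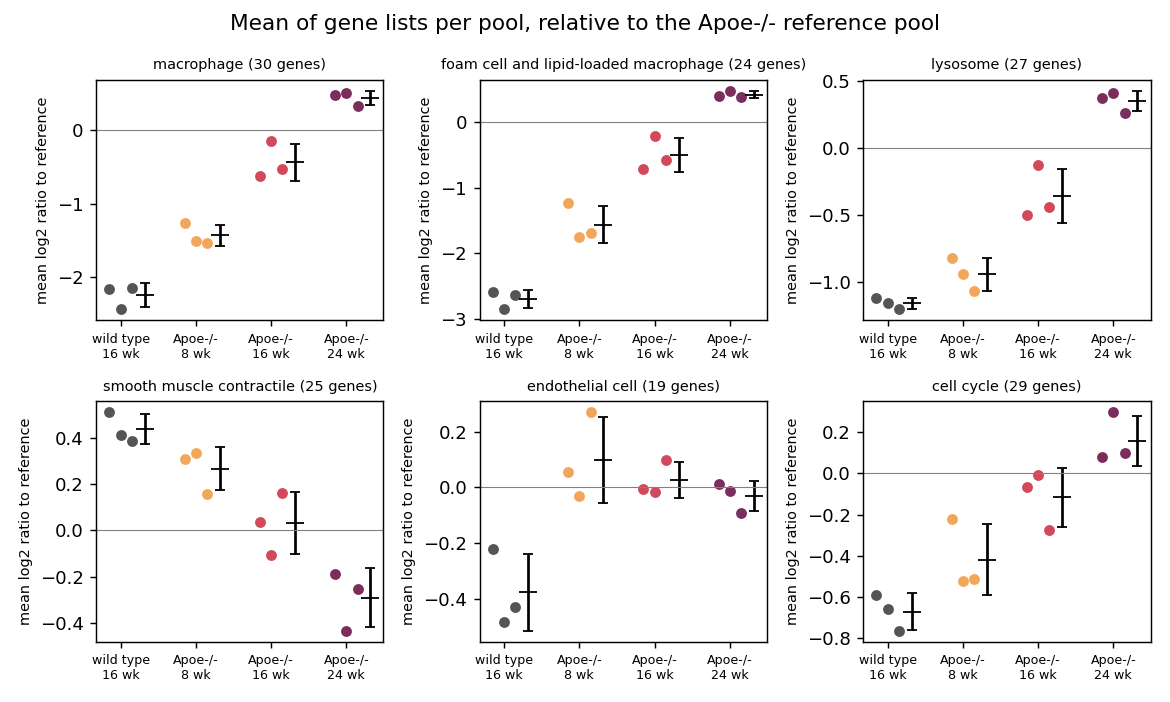
Mean log2 ratio to the Apoe-/- reference of 6 gene lists (vertical axes) in each pool (points) by group (horizontal axes), with the group mean and SD over 3 pools in black. The macrophage list had a mean of -2.24 in the wild type pools and the smooth muscle list was highest there.

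Lists of lymphocytes, neutrophils and blood rose less evenly. Of 17 T cell genes, 4 rose (4 adjusted over the list alone), led by the interleukin-7 receptor Il7r, 16.5-fold, and Cd5, 2.15-fold. Their mean was 0.55 ± 0.08 (camera adjusted p = 0.000817, and adjusted p = 0.164 with an estimated correlation). Of 15 B cell genes, 2 rose (2 adjusted over the list alone), Cd22 12.7-fold and Blnk 3.82-fold. Cd79a, a subunit of the B cell receptor, did not move (0.007 ± 0.097, limma adjusted p = 0.984). The rise of Cd22 and Blnk therefore does not show that B cells were more abundant. The mean of the list was 1.05 ± 0.39 (camera adjusted p = 0.000109, and adjusted p = 0.238 with an estimated correlation). This list's mean ratio was 1.09 in pool 4, against -0.51 in pool 5, -0.56 in pool 6 and -0.94 to -1.16 in the wild type pools, and Blnk had the opposite sign after quantile normalization (-0.11). Of 14 neutrophil genes, 2 rose (3 adjusted over the list alone), Cxcr2 4.58-fold and S100a8 4.83-fold. Their mean was 0.52 ± 0.18 (camera adjusted p = 0.0323, and adjusted p = 0.212 with an estimated correlation). The neutrophil call was lost without pool 18 (adjusted p = 0.0993), and that of S100a8 without pool 4, 17 or 18 (adjusted p up to 0.0951). The list of erythroid genes passed (mean 0.75 ± 0.29, camera adjusted p = 0.00526, and adjusted p = 0.313 with an estimated correlation) although no single gene of its 8 did, against 3 adjusted over the list alone.

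Contractile smooth muscle genes fell at 16 weeks while endothelial genes rose. Of 25 smooth muscle genes, 13 fell and 12 did not pass (19 fell when adjusted over the list alone), with a mean of -0.41 ± 0.09 (camera adjusted p = 4.64e-09, and adjusted p = 0.0739 with an estimated correlation). Ppp1r14a, an inhibitor of myosin phosphatase, was 2.31-fold lower, Myh11, smooth muscle myosin, 1.88-fold, Rbpms 1.60-fold and Mylk, myosin light chain kinase, 1.42-fold lower. Mylk averaged 3 probes that moved by -0.92 to -0.06, of which only 1 passed. Of 19 endothelial genes, 8 rose (10 adjusted over the list alone), among them Egfl7 1.82-fold, Tie1 1.78-fold and Mmrn2 1.75-fold. Their mean was 0.40 ± 0.09 (camera adjusted p = 7.53e-06, and adjusted p = 0.164 with an estimated correlation). Of 29 matrix genes, 5 rose and 3 fell (9 and 3 adjusted over the list alone), with a mean of 0.17 ± 0.07 (camera adjusted p = 0.0264, and adjusted p = 0.478 with an estimated correlation). Col8a1, a short-chain collagen, rose 2.83-fold and Ltbp2 2.18-fold, while Col18a1 was 1.54-fold lower. The proteoglycans Prelp and Bgn also fell, with calls lost on leaving out 3 and 10 of the 12 pools in turn (adjusted p up to 0.0656 and 0.188), and the matrix list lost its call without pool 5 or 18 (adjusted p = 0.068 and 0.175). Of 23 matrix proteases and inhibitors, 11 rose and 2 fell (14 and 2 adjusted over the list alone), with Adam8 6.62-fold and the urokinase Plau 5.16-fold higher, and the metalloproteases Mmp23 1.52-fold and Adamts5 1.19-fold lower. Their mean was 1.04 ± 0.12 (camera adjusted p = 6.96e-08, and adjusted p = 0.0787 with an estimated correlation). The fall of Adamts5 was lost without pool 4, 6, 16 or 17 (adjusted p up to 0.0881), and its 3 probes moved by -0.48 to 0.07, of which 2 passed. Of 23 cartilage and bone genes, 5 rose (6 rose and 1 fell when adjusted over the list alone), including the bone matrix proteins Ibsp 10.7-fold and Spp1 10.6-fold and the decoy receptor Tnfrsf11b 3.71-fold. Their mean was 0.60 ± 0.14 (camera adjusted p = 0.00487, and adjusted p = 0.223 with an estimated correlation).

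Lipid, proliferation and stress genes also moved at 16 weeks. Of 15 targets of the sterol receptor LXR, 8 rose and 1 fell (10 and 2 adjusted over the list alone), with the phospholipid transfer protein Pltp 2.76-fold and the receptor Nr1h3 1.92-fold higher, while Apoe, itself a target, fell. Their mean was 0.53 ± 0.06 (camera adjusted p = 2.21e-05, and adjusted p = 0.0642 with an estimated correlation). Of 17 cholesterol synthesis genes, 5 fell (7 lower and 1 higher adjusted over the list alone), including Lss 1.53-fold and Tm7sf2 1.41-fold. Their mean was -0.20 ± 0.06 (camera adjusted p = 0.0409, and adjusted p = 0.37 with an estimated correlation). That call was lost without pool 2, 3, 5 or 18 in turn (adjusted p = 0.0545, 0.0536, 0.176 and 0.106). Of 29 cell cycle genes, 16 rose (18 higher and 1 lower adjusted over the list alone), with the proliferation marker Mki67 2.59-fold and Cdk1 2.10-fold higher. Their mean was 0.55 ± 0.11 (camera adjusted p = 1.81e-11, and adjusted p = 0.181 with an estimated correlation). Of 25 interferon response genes, 9 rose (19 higher and 1 lower adjusted over the list alone), led by Rsad2 3.64-fold. Their mean was 0.51 ± 0.12 (camera adjusted p = 2.17e-08, and adjusted p = 0.182 with an estimated correlation). Of 23 complement and coagulation genes, 8 rose, with the coagulation factor F7 9.50-fold and the complement component C3 3.51-fold higher, and the tissue factor gene F3 was 1.61-fold lower (8 and 3 adjusted over the list alone, mean 0.54 ± 0.09, camera adjusted p = 0.000198, and adjusted p = 0.212 with an estimated correlation). Of 24 genes of the unfolded protein and oxidative stress responses, 6 rose (6 adjusted over the list alone), including heme oxygenase Hmox1 5.07-fold and the chaperone Dnajb9 2.39-fold. Their mean was 0.32 ± 0.10 (camera adjusted p = 0.000717, and adjusted p = 0.212 with an estimated correlation). Of 20 white adipocyte genes, 3 rose (5 adjusted over the list alone), among them lipoprotein lipase, Lpl, 4.25-fold, which macrophages also express, and adipsin, Cfd, 3.82-fold. Their mean was 0.46 ± 0.11 (camera adjusted p = 0.00031, and adjusted p = 0.217 with an estimated correlation).

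Of the largest falls at 16 weeks, Bcam and Zfp111 lay within the 100 tested genes on each side of Apoe on chromosome 7, 3 and 28 genes away. The positions of the other falls named here were not looked up beyond that window, so some may lie further along the same chromosome. Mrps12, of the mitochondrial ribosome, was 6.38-fold lower (-2.67 ± 0.12, adjusted p = 2.48e-06) and Vmn2r29, a vomeronasal receptor gene, 6.04-fold lower. The zinc finger genes Zfp74, Zfp111 and Zfp420 were 3.88-fold, 3.73-fold and 2.40-fold lower, and the laminin receptor gene Bcam was 3.24-fold lower. The value of Zfp420 averaged 2 probes that moved by -2.75 and 0.22, of which only 1 passed. The neuropeptide receptor Vipr2 was 2.49-fold lower (adjusted p = 0.00159, and 0.0734 or more after quantile normalization), the axon guidance gene Sema3a 2.37-fold (adjusted p = 0.00134) and C1qtnf3 2.37-fold (adjusted p = 0.0297). The call of C1qtnf3 was lost without pool 4, 6, 16 or 17 (adjusted p up to 0.122), after quantile normalization (0.12) and without pools 3 and 6 together (0.114). Of the 67 measured genes of the list flanking Apoe, 13 fell and 4 rose (18 and 5 adjusted over the list alone), and the list as a whole did not pass (mean -0.07 ± 0.03, camera adjusted p = 0.111). Of the 100 genes lower than in wild type at all 3 diet times, 24 were among the 1658 placed on chromosome 7 and at most 6 on any other. Among the 633 tested genes within 400 on either side of Apoe, 5.85% passed in the same direction at all 3 times, against 1.73% of the genes elsewhere, so the excess was not confined to the nearest genes.

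**Figure D2:**
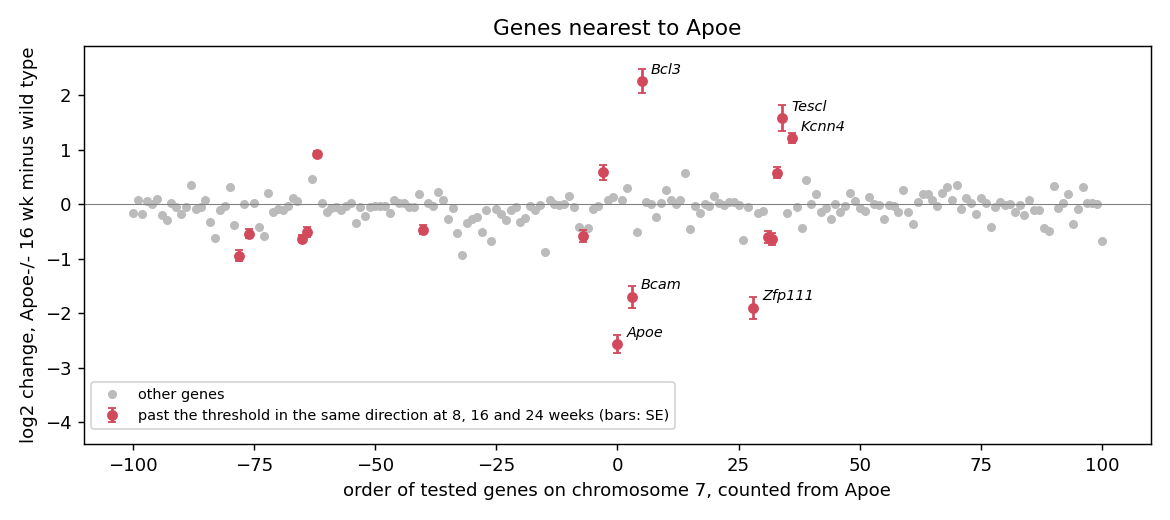
Log2 change at 16 weeks against wild type (vertical axis) of the 100 tested genes on each side of Apoe, by their order on chromosome 7 (horizontal axis). Red points with SE bars are Apoe and the 16 others that passed in the same direction at all 3 diet times, of which 10 were lower.

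The other lists did not pass at 16 weeks. Their means were 0.18 ± 0.16 for thymocyte genes (camera adjusted p = 0.113), 0.12 ± 0.08 for mast cells (0.252), 0.20 ± 0.14 for flow-responsive endothelial genes (0.545), 0.11 ± 0.12 for fibroblasts (0.807), -0.08 ± 0.13 for fatty acid oxidation (0.416), 0.02 ± 0.10 for oxidative phosphorylation (0.723) and 0.003 ± 0.05 for glycolysis and hypoxia (0.807). They were 0.04 ± 0.13 for brown adipocytes (0.971), 0.51 ± 0.62 for cardiac muscle (0.183), 0.06 ± 0.16 for skeletal muscle (0.971), 0.04 ± 0.04 for Schwann cells and nerve (0.917) and -0.10 ± 0.05 for TGF-beta and BMP signalling (0.266). They were 0.15 ± 0.16 for immediate early genes (0.421), -0.17 ± 0.10 for the circadian clock (0.113), 0.05 ± 0.09 for glucocorticoid and fasting genes (0.807) and -0.01 ± 0.07 for sex-linked genes (0.917). The sex-linked list joins Xist with Y-linked genes, and the clock list joins genes of opposite phase. Opposite changes can cancel in such means, so they cannot tell whether sex or time of day was matched. The cardiac mean per pool ranged from -1.62 to -0.43 in wild type and from -1.03 to 0.28 in the 16-week group. In all, 20 of the 39 lists were higher, 2 were lower and 17 did not pass. With an estimated correlation only the macrophage list and that of endothelial activation and adhesion, which includes leukocyte genes, held their calls.

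In total, 1991 of 19705 genes differed at 16 weeks, 1189 higher (59.7%) and 802 lower. Among them, 482 were at least 2-fold higher and 24 at least 2-fold lower. The pools did not overlap for 1989 of the 1991, which selection by a small p nearly ensures (chance gives 10% among unselected genes). The count was 1231 without pool 17, 1254 without pool 4 and 3052 without pool 2. Higher genes were the majority in the reported fit but not in all others: their share was 41.1% of 5604 genes with array weights and 39.9% of 3927 without pools 2 and 18, an alternative chosen after seeing the data. It was 71.4% without pool 16. After quantile normalization the count was 902, with 49.0% higher, and 11 lists no longer passed (adjusted p from 0.0606 to 0.827). Their means were then 0.15 for the lysosomal list, 0.17 for LXR targets, 0.18 for proteases, 0.24 for complement, 0.07 for stress genes, 0.14 for bone and 0.0 for matrix. For B cells the mean was 0.31, for neutrophils 0.30, for erythroid genes 0.31 and for cholesterol synthesis -0.14.

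**Figure D3:**
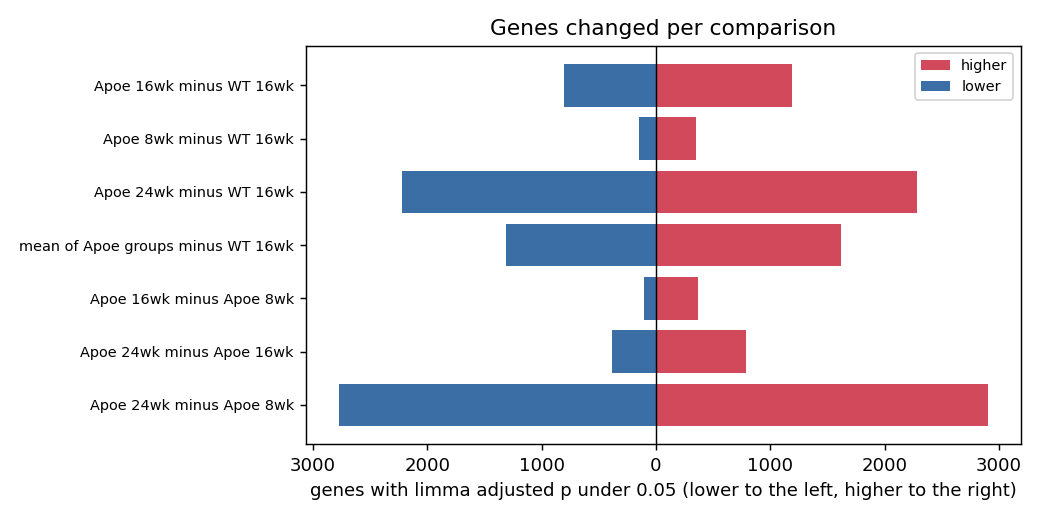
Number of genes with a limma adjusted p under 0.05 in each of 7 comparisons (vertical axis), with those higher in the group named at the start to the right and those lower to the left of 0 (horizontal axis). The count ran from 472 genes for 16 against 8 weeks to 5676 genes for 24 against 8 weeks.

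After 8 weeks of diet, with the wild type mice at 16 weeks, the same kinds of macrophage genes were already higher. Il1rn rose 7.33-fold (2.87 ± 0.28, n = 3 pools per group, confidence interval 4.75 to 11.3, adjusted p = 0.00135), Mmp12 6.08-fold, Abcg1 5.73-fold, Atp6v0d2 5.44-fold and Bcl2a1b 5.41-fold. The falls were Apoe, Mrps12 (5.72-fold), Vmn2r29 (5.20-fold), Zfp74 (4.15-fold) and Zfp111 (3.65-fold). Genotype, length of diet and age changed together here, so the comparison cannot tell them apart. The foam cell list rose (mean 1.13 ± 0.17, 13 of 24 genes higher and 17 adjusted over the list alone, camera adjusted p = 3.5e-16, and adjusted p = 0.148 with an estimated correlation), as did the macrophage list (mean 0.81 ± 0.14, 12 of 30 higher and 21 adjusted over the list alone, camera adjusted p = 1.58e-14, and adjusted p = 0.148 with an estimated correlation), with Itgax 4.31-fold and Mpeg1 5.27-fold higher. Endothelial genes were higher (mean 0.47 ± 0.09, 5 of 19 and 12 adjusted over the list alone, camera adjusted p = 4.8e-08, and adjusted p = 0.148 with an estimated correlation), led by Egfl7 2.19-fold and Tie1 1.83-fold. LXR targets were higher (mean 0.34 ± 0.06, 4 of 15 and 8 adjusted over the list alone, camera adjusted p = 6.13e-05, and adjusted p = 0.148 with an estimated correlation), including Scd1, a fatty acid desaturase, 1.95-fold. White adipocyte genes were higher (mean 0.56 ± 0.11, 5 of 20 and 11 adjusted over the list alone, camera adjusted p = 7.63e-07, and adjusted p = 0.192 with an estimated correlation), including Cfd 4.73-fold and the lipase Pnpla2 1.94-fold. Interferon response genes (mean 0.38 ± 0.12, Rsad2 3.37-fold higher) and endothelial activation genes (mean 0.44 ± 0.08, F11r 1.66-fold higher) passed too, as did chemokines (0.60 ± 0.16), MHC class II (0.44 ± 0.12), T cells (0.39 ± 0.08), B cells (0.44 ± 0.39, Cd22 3.37-fold higher), proteases (0.41 ± 0.12) and erythroid genes (0.90 ± 0.29). None of these calls held with an estimated correlation (adjusted p = 0.148 to 0.514 with an estimated correlation).

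The calls of smaller shifts at 8 weeks depended on single pools, apart from that of TGF-beta and BMP signalling, although some of the shifts stayed as large without the pool. The smooth muscle list was lower (-0.17 ± 0.09, camera adjusted p = 0.00579), with 1 of 25 genes past the threshold and 6 adjusted over the list alone, and lost its call without pool 3 (adjusted p = 0.0742). The brown adipocyte list was higher (0.36 ± 0.13, camera adjusted p = 0.00579), and its call was also lost without pool 3 (adjusted p = 0.124). The lysosomal list (0.22 ± 0.10) and the cell cycle list (0.25 ± 0.11) were higher and lost their calls without pool 1 (adjusted p = 0.0946 and 0.058). Oxidative phosphorylation (0.12 ± 0.10) was lost without pool 1 or 3 (adjusted p = 0.178 and 0.051) and the thymocyte list (0.32 ± 0.16) without pool 1, 3 or 18 (adjusted p = 0.211, 0.124 and 0.0872). The circadian clock list was lower (-0.23 ± 0.10) and lost its call without pool 2, 3 or 18 (adjusted p = 0.066, 0.051 and 0.0562). Its shift was then -0.10, -0.27 and -0.26, and that of the thymocyte list was 0.33 without pool 18. TGF-beta and BMP signalling was lower (-0.16 ± 0.05, camera adjusted p = 0.0065) with no gene of its 24 past the threshold. None of the 21 lists that passed at 8 weeks kept its call with an estimated correlation (adjusted p = 0.148 to 0.514 with an estimated correlation), 13 were lost with fry, and the 18 others did not pass (camera adjusted p from 0.054).

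In total, 492 genes differed at 8 weeks, 347 higher (70.5%) and 145 lower, and the pools did not overlap for any of them. The count was 137 without pool 17, 222 without pool 16, 317 without pool 11 and 760 without pool 18. Higher genes were no longer the majority without pool 18 (47.5%) or without pools 2 and 18 together (42.9% of 1359), the latter an alternative chosen after seeing the data. With only the 2 groups in the fit the count was 29, and Bcl2a1b, Il1rn and Mmp12 (adjusted p from 0.0501 to 0.0665) and the fall of Zfp111 (0.0501) lost their calls. After quantile normalization it was 8, all lower, when Zfp111 did not pass (0.0598), none of the 5 named rises did (adjusted p from 0.051 to 0.49) and the lysosomal list changed sign (-0.03). The macrophage list then had a mean of 0.10 (adjusted p = 0.19), chemokines 0.20 (0.0961), MHC class II 0.14 (0.181), B cells 0.12 (0.362) and proteases 0.02 (0.989), and none of these passed.

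After 24 weeks of diet, macrophage, foam cell, lysosomal and smooth muscle genes stood further from wild type at 16 weeks, again with genotype, length of diet and age changed together. The endothelial (0.35 ± 0.09), erythroid (0.83 ± 0.29), white adipocyte (0.34 ± 0.11) and brown adipocyte lists (-0.09 ± 0.13) stood no further than at 8 weeks, and the adipocyte lists did not pass (camera adjusted p = 0.12 and 0.361). Mmp12 was 105-fold higher (6.72 ± 0.34, n = 3 pools per group, confidence interval 62.9 to 176, adjusted p = 4.53e-07), Ctss 84.6-fold, Bex1 79.4-fold, Atp6v0d2 69.9-fold and Lilrb4a 65.7-fold. The largest falls were those of Bcam (5.59-fold), Mrps12 (5.46-fold), Vmn2r29 (5.37-fold), Apoe and Zfp111 (4.11-fold). Of 30 macrophage genes, 27 rose (27 adjusted over the list alone, mean 2.68 ± 0.14, camera adjusted p = 1.25e-25, and adjusted p = 0.0615 with an estimated correlation), and of 24 foam cell genes 22 rose (22 adjusted over the list alone, mean 3.11 ± 0.17, camera adjusted p = 4.38e-26, and adjusted p = 0.0615 with an estimated correlation). Of 27 lysosomal genes, 23 rose (24 adjusted over the list alone), with Npc2 4.26-fold and Lamp2 3.56-fold higher. Their mean was 1.51 ± 0.10 (camera adjusted p = 8.8e-21, and adjusted p = 0.0615 with an estimated correlation). Of 23 matrix proteases and inhibitors, 14 rose and 2 fell (14 and 2 adjusted over the list alone), with the collagenase Mmp13 30.6-fold and Adam8 21.2-fold higher, while Mmp23 was 1.40-fold lower. Their mean was 1.77 ± 0.12 (camera adjusted p = 1.06e-09, and adjusted p = 0.0615 with an estimated correlation). Of 25 smooth muscle genes, 17 fell (19 adjusted over the list alone), with Ppp1r14a 3.11-fold, Cnn1, calponin, 2.58-fold and Rbpms 2.33-fold lower. Their mean was -0.73 ± 0.09 (camera adjusted p = 3.23e-10, and adjusted p = 0.0615 with an estimated correlation). Of 29 cell cycle genes, 23 rose (23 higher and 1 lower adjusted over the list alone), with Mki67 4.34-fold and Kif11 2.80-fold higher. Their mean was 0.83 ± 0.11 (camera adjusted p = 5.37e-13, and adjusted p = 0.143 with an estimated correlation).

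Further lists passed at 24 weeks. Chemokines rose (mean 1.60 ± 0.16, 19 of 30 genes, and 23 higher and 2 lower adjusted over the list alone, camera adjusted p = 4.5e-13, and adjusted p = 0.0651 with an estimated correlation), with Ccl3 14.3-fold and Ccl2 12.8-fold higher. Stress genes rose (mean 0.66 ± 0.10, 14 of 24 higher and 1 lower, 16 and 3 adjusted over the list alone, camera adjusted p = 3.36e-07, and adjusted p = 0.0796 with an estimated correlation), with Hmox1 8.88-fold higher. Complement genes (0.80 ± 0.09, F7 13.9-fold higher, F3 1.47-fold lower), LXR targets (0.80 ± 0.06, Abcg1 43.0-fold higher), endothelial activation (1.08 ± 0.08, Vcam1 17.4-fold higher), MHC class II (1.34 ± 0.12, Cd83 6.10-fold higher), interferon response (0.59 ± 0.12, Bst2 2.15-fold higher) and T cell genes (0.71 ± 0.08, Il7r 53.9-fold higher) rose (adjusted p = 0.0615 to 0.208 with an estimated correlation). Cartilage and bone genes rose (0.94 ± 0.14), with Spp1 49.4-fold, Ibsp 31.4-fold and the bone transcription factor Runx2 2.79-fold higher, as did endothelial (0.35 ± 0.09, Mmrn2 1.72-fold higher), matrix (0.39 ± 0.07, Col8a1 4.82-fold higher, Col18a1 2.09-fold lower), neutrophil (0.54 ± 0.18, Cxcr2 3.96-fold higher) and erythroid lists (0.83 ± 0.29). None of these held with an estimated correlation (adjusted p = 0.208 to 0.367 with an estimated correlation). After quantile normalization the bone (adjusted p = 0.0549), neutrophil (0.0738), erythroid (0.305) and flow-responsive endothelial lists (0.0581) did not pass. Cholesterol synthesis fell (-0.32 ± 0.06, and adjusted p = 0.32 with an estimated correlation), with Srebf2, its main transcription factor, 2.20-fold lower, and the list flanking Apoe fell (-0.14 ± 0.03, and adjusted p = 0.355 with an estimated correlation), with Slc1a5 1.59-fold and Dmpk 2.87-fold lower and Bcl3 6.69-fold, Plaur, Calm3, Ptgir and Apoc2 higher. Kcnn4 was higher as the mean of 3 probes, which moved by 0.11 to 2.80 and of which 2 passed. The flow-responsive endothelial list (0.58 ± 0.14, with the endothelin gene Edn1 2.66-fold higher and Asb2 2.16-fold lower) lost its call without pool 6 (adjusted p = 0.0527), and glycolysis (0.15 ± 0.05, Pdk1 1.74-fold higher) without pool 12 (adjusted p = 0.0551). None of the 23 lists that passed kept its call with an estimated correlation (adjusted p = 0.0615 to 0.367 with an estimated correlation), and 16 did not pass (camera adjusted p from 0.11). Against their lists, Adamts5, Col9a1, Nr1h2, Sod1 and Loxl1 fell and Dhcr7 rose. These 6 calls were lost without single pools, Loxl1 without pool 12 (adjusted p = 0.0597), Nr1h2 without 11 or 12 (up to 0.0658), Dhcr7 without 10, 11, 16 or 17 (up to 0.0747) and Sod1 without 11, 12, 16, 17 or 18 (up to 0.103). Adamts5 was lost without 9 of the 12 pools (up to 0.146) and Col9a1 without 8 (up to 0.132). In total, 4504 genes differed, 2285 higher (50.7%) and 2219 lower, with no overlap of pools for 4497, and the share of higher genes was 60.7% with median-centred arrays, 41.0% of 8180 genes with array weights and 45.0% of 6237 without pool 2.

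The mean of the Apoe-/- groups, which weighs the 3 diet times equally, differed from wild type in 2927 genes, 1620 higher (55.3%) and 1307 lower, and the 9 Apoe-/- pools did not overlap with the wild type pools for 1434 of the 2927. The share of higher genes was 64.4% with median-centred arrays, 49.8% without pool 18, 41.8% of 5969 genes with array weights and 42.3% of 4265 without pools 2 and 18, so that majority did not hold throughout. Mmp12 was 26.2-fold higher (4.71 ± 0.28, confidence interval 17.2 to 39.9, adjusted p = 2.23e-06), Bex1 24.5-fold, Atp6v0d2 22.0-fold, Ctss 20.8-fold and Il1rn 20.5-fold, and Mrps12 was 5.84-fold, Vmn2r29 5.53-fold, Zfp74 3.96-fold and Zfp111 3.83-fold lower. Of the lists, 21 were higher and 2, smooth muscle (-0.43 ± 0.07) and cholesterol synthesis (-0.23 ± 0.05), were lower. The macrophage list (1.77 ± 0.12) and that of endothelial activation and adhesion (0.77 ± 0.06) kept their calls with an estimated correlation (adjusted p = 0.0467 with an estimated correlation for each), and the other 21 did not (up to adjusted p = 0.343 with an estimated correlation). The count was 1637 without pool 17 and 1905 without pool 16, and 1797 after quantile normalization. The thymocyte list (0.24 ± 0.13) lost its call without pool 1, 3, 5, 17 or 18 (adjusted p = 0.07, 0.0512, 0.0678, 0.0811 and 0.066) and the neutrophil list (0.49 ± 0.14) without pool 18 (adjusted p = 0.066). After quantile normalization the thymocyte (adjusted p = 0.119), B cell (0.211), erythroid (0.0713), matrix (0.0694) and bone lists (0.143) did not pass.

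The 3 comparisons with wild type called 370 genes in common, 269 higher and 100 lower in all 3 and 1 in different directions. At 8 and 16 weeks, 291 genes were higher and 115 lower in both comparisons, where independent lists of those sizes share 20.9 and 5.90. The changes correlated across genes with r = 0.753, against 0.50 for simulated unchanged groups that share the 3 wild type pools, and their covariance was 0.0883 against a simulated 0.0109. At 16 and 24 weeks, 1111 genes were higher and 619 lower in both, where independent lists share 138 and 90.3 (r = 0.886 against a simulated 0.503, covariance 0.197 against 0.0110). At 8 and 24 weeks, 273 were higher and 112 lower in both, where independent lists share 40.2 and 16.3 (r = 0.525 against a simulated 0.499, covariance 0.0864 against 0.0109). Over all genes, 72.3% had the same sign at 8 and 16 weeks and 75.2% at 16 and 24 weeks, against a simulated 66.5%. At 8 and 24 weeks it was 58.4%, below the simulated 66.6%, with a rank correlation of 0.232. Simulated comparisons shared at most 0.05 calls on average. The 3 wild type pools cannot be split into parts of at least 2, so part of the excess may come from the shared controls, and genes are not independent replicates. A pair of comparisons with no pool in common, 16 weeks against wild type and 24 against 8 weeks, shared 883 higher and 376 lower genes, where independent lists share 175 and 113, with 55 genes in opposite directions (r = 0.573, and 57.2% of all genes with the same sign). The other such pair, 8 weeks against wild type and 24 against 16 weeks, shared 103 higher and 23 lower genes, where independent lists share 13.8 and 2.85, with 14 in opposite directions. Over all genes this pair did not go together (r = -0.024, rank correlation -0.229, and 41.2% with the same sign against a simulated 50%).

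Between 8 and 16 weeks of diet the largest rises in the Apoe-/- arch were those of Ibsp, bone sialoprotein, 8.24-fold (3.04 ± 0.29, n = 3 pools per group, confidence interval 5.33 to 12.8, adjusted p = 0.00377), Bex1 8.08-fold, Il7r 5.39-fold, Atp6v0d2 5.16-fold and Rnf128 5.14-fold. Smim5 was 2.25-fold lower (adjusted p = 0.00513), the surfactant gene Sftpc 2.41-fold, Gkn3 2.18-fold, and the homeobox genes Hoxc6 and Hoxb8 1.87-fold and 1.80-fold lower. These calls except that of Smim5 were lost on leaving out single pools: Sftpc without pool 4, 5 or 6, Gkn3 without 1, 3, 4 or 6, Hoxc6 without 4 or 5, and Hoxb8 without 1, 3, 4 or 5 (adjusted p up to 0.108, 0.122, 0.056 and 0.0981). None of the 5 rises passed after quantile normalization (adjusted p from 0.132 to 0.344) or with only the 2 groups in the fit (0.0858 each), and none of the 5 falls did (from 0.136 to 0.498, and from 0.0858 to 0.188). Without pools 3 and 6, the calls of Il7r and Rnf128 (adjusted p from 0.0538 to 0.0645) and of Gkn3, Hoxb8 and Hoxc6 (from 0.0535 to 0.166) were lost as well. Of 30 macrophage genes, 19 rose (22 adjusted over the list alone, mean 0.99 ± 0.14, camera adjusted p = 2.94e-21, and adjusted p = 0.122 with an estimated correlation), with Lgals3 and Fcgr3 3.17-fold higher each. Foam cell genes rose (mean 1.06 ± 0.17, 14 of 24 and 18 adjusted over the list alone, camera adjusted p = 3.76e-21, and adjusted p = 0.122 with an estimated correlation), with Gpnmb 3.58-fold higher, and so did lysosomal genes (mean 0.58 ± 0.10, 12 of 27 and 19 adjusted over the list alone, camera adjusted p = 5.88e-17, and adjusted p = 0.122 with an estimated correlation), with Npc2 2.08-fold higher. Proteases (0.63 ± 0.12, Adam8 3.05-fold higher), MHC class II (0.62 ± 0.12), chemokines (0.53 ± 0.16, Ccl3 2.58-fold higher), endothelial activation (0.37 ± 0.08, Cd44 1.47-fold higher), cartilage and bone (0.48 ± 0.14, Spp1 3.51-fold higher, and adjusted p = 0.23 with an estimated correlation), complement (0.30 ± 0.09, F7 3.02-fold higher), stress (0.26 ± 0.10, Dnajb9 1.71-fold higher) and cell cycle lists (0.30 ± 0.11) rose, the last with no gene of its 29 past the threshold and 3 adjusted over the list alone. None of these held with an estimated correlation (adjusted p = 0.122 to 0.345 with an estimated correlation), and after quantile normalization proteases (0.17, adjusted p = 0.13) and stress genes (0.06, adjusted p = 0.445) did not pass. Smooth muscle genes fell (-0.24 ± 0.09, 4 of 25 and 11 adjusted over the list alone, camera adjusted p = 1.66e-07, and adjusted p = 0.122 with an estimated correlation), with Rbpms 1.58-fold lower, as did brown adipocyte genes (-0.31 ± 0.13, and adjusted p = 0.191 with an estimated correlation), with the transcription factor Prdm16 1.62-fold lower.

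Other calls between 8 and 16 weeks depended on single pools. The B cell list (0.61 ± 0.39) was lost without pool 4 or 1 (adjusted p = 0.63 and 0.103), and the fibroblast list (0.24 ± 0.12, with the proteoglycan Lum 3.52-fold higher) without pool 5, 1 or 2 (adjusted p = 0.356, 0.119 and 0.0989). Neither passed after quantile normalization (adjusted p = 0.197 and 0.0723). Oxidative phosphorylation (-0.09 ± 0.10) was lost without pool 4, 5, 1 or 3 (adjusted p = 0.127, 0.549, 0.257 and 0.0555), and the interferon list (0.13 ± 0.12) without pool 4, 5, 10, 1 or 3 (adjusted p = 0.0679, 0.294, 0.0508, 0.0943 and 0.263). None of the 17 lists that passed kept its call with an estimated correlation (adjusted p = 0.122 to 0.678 with an estimated correlation), and 22 did not pass (camera adjusted p from 0.0524). In total, 472 genes differed, 372 higher (78.8%) and 100 lower, with no overlap of pools for any. The count was 167 without pool 5, 246 without pool 4 and 758 without pool 1. It was 1, a higher gene, after quantile normalization and 0 by limma on these 2 groups alone, where 1914 genes had an unadjusted p under 0.05, against 2969 in the fit of all groups. No other tool was run.

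Between 16 and 24 weeks the largest rises were those of Spp1, osteopontin, 4.64-fold (2.21 ± 0.28, n = 3 pools per group, confidence interval 3.04 to 7.09, adjusted p = 0.00392), Ctss 4.14-fold, Mmp12 3.73-fold, the fungal receptor Clec7a 3.71-fold and Plek, a platelet and leukocyte protein, 3.70-fold. The largest falls were those of the fibrinogen gene Fgb, 2.32-fold, the Wnt effector Tcf7l2, 2.29-fold, the potassium channel Kcnc4, 2.22-fold, smoothelin, Smtn, 2.14-fold, and Rab17, 1.95-fold. Without single pools, Mmp12 (4, 6, 11 or 12), Clec7a (4, 6 or 11), Smtn (4, 6 or 12), Rab17 (4, 11 or 12) and Fgb (8 of the 12 pools) lost their calls, with adjusted p up to 0.0698, 0.0811, 0.0698, 0.0589 and 0.198. Without pools 1, 4 and 10, all 5 falls (adjusted p from 0.0557 to 0.186), Clec7a and Plek (from 0.0621 to 0.129) did not pass, and without pools 3 and 6 Clec7a and Mmp12 (from 0.0549 to 0.0837) and Fgb and Smtn (from 0.0577 to 0.0805) did not. Tcf7l2 averaged 2 probes that moved by -2.25 and -0.15, of which only 1 passed. Lysosomal genes rose (mean 0.71 ± 0.10, 18 of 27 and 19 adjusted over the list alone, camera adjusted p = 2.97e-16, and adjusted p = 0.158 with an estimated correlation), with Gusb 2.89-fold, the collagen-degrading cathepsin Ctsk 2.55-fold and Lamp2 2.11-fold higher. Macrophage genes rose (0.87 ± 0.14, 17 of 30, and 23 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.78e-15, and adjusted p = 0.158 with an estimated correlation), with Lyz1, lysozyme, 2.73-fold and Cd14 2.69-fold higher, and foam cell genes rose (0.92 ± 0.17, 14 of 24 and 20 adjusted over the list alone, camera adjusted p = 1.13e-15, and adjusted p = 0.158 with an estimated correlation), with Plin2, of lipid droplets, 1.87-fold higher. Proteases (0.73 ± 0.12, Adam8 3.20-fold higher), chemokines (0.47 ± 0.16, Ccl9 1.92-fold higher), stress (0.35 ± 0.10), complement (0.26 ± 0.09, clusterin, Clu, 2.27-fold higher) and cell cycle lists (0.27 ± 0.11, no gene of 29 past the threshold and 5 adjusted over the list alone) rose. None of these held with an estimated correlation (adjusted p = 0.158 to 0.482 with an estimated correlation). Smooth muscle genes fell (-0.32 ± 0.09, 8 of 25 and 11 adjusted over the list alone, camera adjusted p = 2.67e-07, and adjusted p = 0.158 with an estimated correlation), with Cnn1 1.75-fold and Rbpms 1.46-fold lower.

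The LXR list (0.27 ± 0.06) and the flow-responsive list (0.38 ± 0.14) rose between 16 and 24 weeks but lost their calls without pool 5 (adjusted p = 0.0534 each) or 10 (adjusted p = 0.105 and 0.0528), glycolysis (0.15 ± 0.05) without pool 5 (adjusted p = 0.0535) and the matrix list (0.21 ± 0.07) without pool 6 (adjusted p = 0.0603). Col18a1 fell against that list, a call lost without pool 4, 5, 6, 11 or 12 (adjusted p up to 0.126). None of the 13 lists that passed kept its call with an estimated correlation (adjusted p = 0.158 to 0.534 with an estimated correlation), and 26 did not pass (camera adjusted p from 0.0555). In total, 1172 genes differed, 785 higher (67.0%) and 387 lower, with no overlap of pools for any. The count was 119 without pool 4, 144 without pool 11, 203 without pool 12, 266 without pool 6, 676 without pool 10 and 2572 without pool 2. It was 3328 with only the 2 groups in the fit and 4866, with 53.9% higher, after quantile normalization. With array weights the share of higher genes was 49.6%.

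Over the whole span from 8 to 24 weeks, Ibsp rose 24.2-fold (4.60 ± 0.29, n = 3 pools per group, confidence interval 15.6 to 37.4, adjusted p = 1.07e-05), Il7r 17.5-fold, Rnf128 and Mmp12 17.3-fold each and Bex1 16.6-fold. The TGF-beta binding protein gene Ltbp1 was 3.84-fold lower, Smim5 3.73-fold, Kcnc4 and Rab17 3.52-fold each and Hoxd11 3.32-fold lower. Of 30 macrophage genes, 25 rose, with Fcgr3 6.63-fold higher, and Itgam, an integrin of myeloid cells, fell (26 and 2 adjusted over the list alone, mean 1.87 ± 0.14, camera adjusted p = 5.92e-18, and adjusted p = 0.129 with an estimated correlation). The fall of Itgam was lost without 8 of the 12 pools in turn (adjusted p up to 0.138). Of 24 foam cell genes, 21 rose (22 adjusted over the list alone, mean 1.98 ± 0.17, camera adjusted p = 5.92e-18, and adjusted p = 0.129 with an estimated correlation), with Spp1 16.3-fold and the acyltransferase Soat1 6.48-fold higher. Of 27 lysosomal genes, 22 rose (24 adjusted over the list alone, mean 1.29 ± 0.10, camera adjusted p = 6e-17, and adjusted p = 0.129 with an estimated correlation), with Gusb 6.16-fold higher. Of 25 smooth muscle genes, 16 fell (17 adjusted over the list alone, mean -0.56 ± 0.09, camera adjusted p = 7.71e-08, and adjusted p = 0.129 with an estimated correlation), with Myl9 2.38-fold and Cnn1 2.31-fold lower. Of 29 cell cycle genes, 21 rose and 1 fell (25 and 1 adjusted over the list alone, mean 0.58 ± 0.11, camera adjusted p = 1.23e-08, and adjusted p = 0.299 with an estimated correlation), with Mki67 2.81-fold higher, while Kif23 was 1.52-fold lower, a call lost without pool 2, 11 or 12 (adjusted p up to 0.111). Of 29 matrix genes, 11 rose, with fibronectin, Fn1, 3.87-fold and Col8a1 3.15-fold higher, and 7 fell, namely Col18a1 2.00-fold, Loxl1 1.55-fold, Col4a2 1.47-fold, Eln, elastin, 1.63-fold, Col4a1, Col6a1 and Col6a2 (11 and 7 adjusted over the list alone, mean 0.31 ± 0.07, camera adjusted p = 0.0378, and adjusted p = 0.604 with an estimated correlation).

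The last 4 of those matrix genes lost their calls without single pools, Eln without 2, 10 or 11, Col4a1 without 10 or 11, Col6a1 without 6 of the 12 and Col6a2 without 2, 11 or 12 (adjusted p up to 0.0871, 0.0656, 0.126 and 0.0857), as did Ltbp1 without 11 and Hoxd11 without 2 or 11 (adjusted p up to 0.0545 and 0.0694). Proteases (1.36 ± 0.12, Mmp13 14.8-fold higher), chemokines (1.00 ± 0.16, Ccl3 6.85-fold higher), MHC class II (0.89 ± 0.12, Cd83 5.17-fold higher), endothelial activation (0.65 ± 0.08, Vcam1 7.56-fold higher), complement (0.56 ± 0.09, Clu 2.88-fold higher) and stress genes (0.60 ± 0.10, the chaperone Hspa5 3.51-fold higher) rose, and brown adipocyte genes fell (-0.45 ± 0.13, Prdm16 2.42-fold and Cidea 3.24-fold lower). None of these held with an estimated correlation (adjusted p = 0.129 to 0.259 with an estimated correlation). The matrix list was lost without pool 3 (adjusted p = 0.115), cartilage and bone (0.81 ± 0.14) without pool 1 or 3 (adjusted p = 0.0527 and 0.0578), the list flanking Apoe (-0.14 ± 0.03) without pool 12 (adjusted p = 0.0527), LXR targets (0.46 ± 0.06) without pool 6, 10, 1 or 3 (adjusted p = 0.0587, 0.0936, 0.0913 and 0.0841) and interferon genes (0.22 ± 0.12) without pool 10, 11, 1 or 3 (adjusted p = 0.0887, 0.0701, 0.0601 and 0.11). The matrix, LXR and interferon lists did not pass after quantile normalization either (adjusted p = 0.051 each). Against their lists, Abcg8, an LXR target, was 1.26-fold lower, and Bcl3 2.17-fold and Plaur 1.76-fold higher. The 3 probes of Kcnn4, which also rose, moved by 0.41 to 1.79. Icam2, Alpl, Trpv4 and Sod1 fell and Calm3, Ptgir and Ap2s1 rose against theirs, each with a call lost without at least 2 single pools (adjusted p up to 0.111, 0.101, 0.141, 0.145, 0.0813, 0.0631 and 0.0919), and the 2 probes of Calm3 moved in opposite directions (-0.52 and 0.93). None of the 17 lists that passed kept its call with an estimated correlation (adjusted p = 0.129 to 0.669 with an estimated correlation), and 22 did not pass (camera adjusted p from 0.0788). In total, 5676 genes differed, 2904 higher (51.2%) and 2772 lower, with no overlap of pools for 5605. The count was 2955 without pool 11, 3168 without pool 12 and 3266 with only the 2 groups in the fit.

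**Figure D4:**
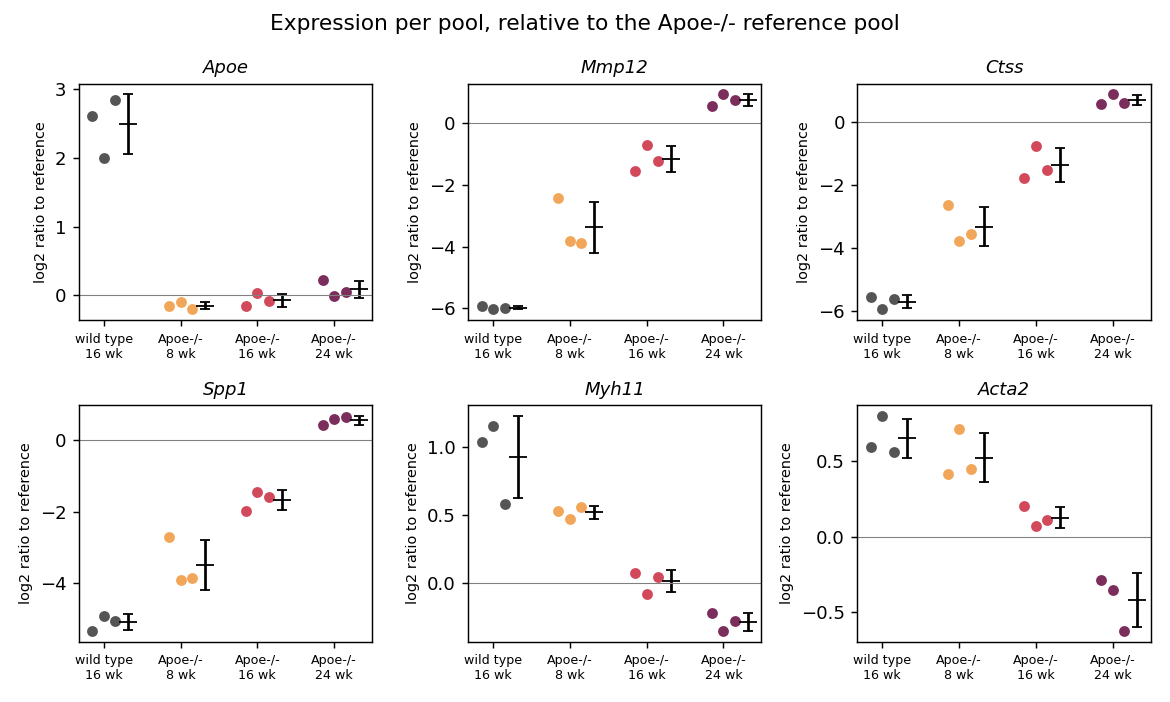
Log2 ratio to the Apoe-/- reference (vertical axes) of 6 genes in each pool (points) by group (horizontal axes), with the group mean and SD over 3 pools in black. Apoe was above 2 in the wild type pools and near 0 elsewhere, while Mmp12, Ctss and Spp1 were lowest in wild type and highest at 24 weeks.

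The F test found 3615 genes that differed among the 3 diet times. Of these, 1929 (53.4%) rose at both steps and 1403 (38.8%) fell at both, 163 fell and then rose, and 120 rose and then fell, by the signs of their means. The smallest adjusted p was that of Nkd1, an inhibitor of Wnt signalling, whose mean ratio was 0.73 at 8 weeks, 0.23 at 16 weeks and -0.53 at 24 weeks (adjusted p = 3.68e-05). Stum, Arhgef17 and Pcp4l1 fell in the same order, Pcp4l1 from 0.82 over 0.18 to -0.55. Adam8, a protease of myeloid cells, rose from -2.57 over -0.96 to 0.72, Kcnk13 from -2.00 over -0.69 to 0.67, and Ibsp from -3.96 over -0.92 to 0.63. Pira2, Gpr137b and Slc37a2 rose as well, and the adjusted p of these 10 genes was at most 3.97e-05. The count was 1840 without pool 11 and 1927 without pool 12.

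Transcripts of other tissues were uneven between pools, and those of Pth, Chga, Prm1, Tnp1 and Jchain marked single pools. Pth, parathyroid hormone, had a log2 ratio of 2.58 in pool 10 and between -4.86 and -3.18 in all others, and Chga, of endocrine cells, 1.94 there and at most -1.07 elsewhere. The sperm genes Prm1 and Tnp1 had ratios of 2.65 and 2.44 in pool 1 and at most -1.89 and -2.15 elsewhere. Jchain, of plasma cells, had 3.31 in pool 4 and at most -1.28 elsewhere. Sftpc, of lung, was raised in all 3 pools at 8 weeks, with 0.89, 0.91 and 2.04 in pools 1, 2 and 3 and at most 0.20 elsewhere. Myl7, of cardiac atria, had 1.80 in pool 6, 0.48 in pool 1 and between -3.64 and -0.04 elsewhere. These 7 genes were chosen after their values were seen. Without pools 1, 4 and 10 together, an alternative chosen after seeing the data, 998 genes differed at 16 weeks against wild type, 71 at 8 weeks, 216 between 8 and 16 weeks and 36 between 16 and 24 weeks.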

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

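The tests in this part, limma on genes or probes and camera on lists, were planned, and looking for opposite directions among their results came only after the results were seen. The shift of the brown adipocyte list against wild type differed in sign between 8 and 24 weeks. It was 0.36 ± 0.13 at 8 weeks, a call lost without pool 3 (adjusted p = 0.124), and -0.09 ± 0.13 at 24 weeks, which did not pass (camera adjusted p = 0.361). The difference of -0.45 ± 0.13 passed (camera adjusted p = 0.00558, and adjusted p = 0.259 with an estimated correlation). The list's mean ratio was 0.32, 0.12 and 0.47 in pools 1, 2 and 3 at 8 weeks and -0.11, -0.30 and -0.03 in pools 10, 11 and 12 at 24 weeks. The white adipocyte list also moved down from 8 to 24 weeks (-0.21 ± 0.11) but did not pass (camera adjusted p = 0.0986), and Sftpc, of lung, was raised in all 3 pools at 8 weeks (0.89, 0.91 and 2.04), so uneven amounts of neighbouring tissue stay open. No explanation of the shift was tested.

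A total of 4 genes were past the threshold in opposite directions against wild type at 8 and 24 weeks, with the difference between the times also past it. Against wild type, Ablim1 differed by 0.35 at 8 weeks and by -0.22 at 24 weeks, a change of -0.58 between the times (adjusted p of that change = 0.000153). Caskin2 differed by 0.35 and -0.49 (change -0.83, adjusted p = 4.29e-05), Dennd3 by 0.39 and -0.23 (change -0.62, adjusted p = 0.000129), and Creld2, of the endoplasmic reticulum, by -0.57 and 0.47 (change 1.05, adjusted p = 0.000135). No explanation was tested.

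Among the 16129 complete probes with no gene name, which entered none of the gene counts and only the alternative that counts single probes, 500 were past the threshold at 16 weeks against wild type, 189 of them higher, with a largest rise of 4.20. The count was 110 at 8 weeks and 1393 at 24 weeks. What these probes measure is not given in the sources used here.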

How the results depend on the processing

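Leaving out pools 2 and 18 together, the arrays farthest from their groups on the second principal component, and leaving out pools 1, 4 and 10 together were chosen only after the data were seen; all other alternatives were planned. Counts below are genes past the threshold by limma. With quantile normalization the count was 902 (16 weeks against wild type), 8 (8 weeks against wild type), 1797 (mean of the Apoe-/- groups), 1 (16 against 8 weeks) and 4866 (24 against 16 weeks). That step gives every array the same distribution of ratios, whose SD ranged from 0.133 to 0.488 as deposited. With array weights, which gave pool 2 a weight of 0.150 and pool 4 one of 2.70, it was 5604 (16 weeks), 8180 (24 weeks), 5969 (mean), 6296 (24 against 16 weeks) and 6623 (F test). With a minimum fold of 1.2 it was 690 (16 weeks), 89 (8 weeks), 1813 (24 weeks), 884 (mean), 88 (16 against 8), 68 (24 against 16) and 1522 (24 against 8), by the stricter null hypothesis. With only the groups compared it was 29 (8 weeks), 0 (16 against 8, with 1914 at an unadjusted p under 0.05), 3328 (24 against 16) and 3266 (24 against 8), where the spread is that of fewer arrays. Without pools 3 and 6 it was 310 (8 weeks), 153 (16 against 8) and 200 (24 against 16). Without pools 2 and 18 it was 3927 (16 weeks), 1359 (8 weeks) and 3970 (24 against 16), and without pools 1, 4 and 10 it was 998 (16 weeks), 71 (8 weeks), 216 (16 against 8), 36 (24 against 16) and 2220 (F test). The wild type arrays against the reference alone gave 5027, where the Apoe-/- pools add no spread. The cause of the other changes was not tested.

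Leaving out each pool in turn gave 1231 to 3052 genes at 16 weeks against wild type, 137 to 760 at 8 weeks, 3105 to 6237 at 24 weeks and 1637 to 4067 for the mean. It gave 167 to 758 for 16 against 8 weeks, 119 to 2572 for 24 against 16, 2955 to 7020 for 24 against 8 and 1840 to 4817 for the F test. Median-centred arrays, the most variable probe, the filter on SD, genes with missing values, robust eBayes and weights by mice per pool left each count within 1.5 times its value. Single probes cannot be set against these counts, since they were counted as probes, 39154 of them with those that carry no gene name (2473 past the threshold at 16 weeks).

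Of 136 calls of lists under 2448 alternatives in all, 2173 alternatives kept the direction and the call, 274 kept the direction and lost the call, 132 of these with an estimated correlation and 27 with fry, and 1 changed direction, the lysosomal list at 8 weeks (-0.033). Against wild type, fry lost 13 calls at 8 weeks, 2 at 16 weeks, 0 at 24 weeks and 1 for the mean. Between diet times it lost 6 for 16 against 8 weeks, 4 for 24 against 16 and 1 for 24 against 8. Of 537 calls of named genes under 13417 alternatives, 12092 kept both, 1320 lost the call and 5 changed direction. These were Blnk (-0.11) and Cd83 (-0.24) at 16 weeks, Adam8 (-0.16) and Il7r (-0.055) at 8 weeks, and Cd83 for 16 against 8 weeks (-0.008), and as for the lysosomal list the alternative was quantile normalization. No paired analysis was possible because each pool number occurs in only 1 group. Signal over background, which could limit all folds, is not known from ratios.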

Other observations

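The tests in this part on genes near Apoe, on differences between lists and on Hox genes were chosen only after the results were seen, apart from the tolerance for probes of genes near Apoe, which was written down before, and the splits of the pools, which were planned. Homeobox genes, which mark position along the body axis, differed between the groups. Of 15 measured Hox genes of paralog groups 4 to 8, 5 were lower at 16 weeks than in wild type (Hoxa7 -0.60, Hoxb5 -0.73, Hoxb6 -1.01, Hoxb8 -0.86 and Hoxc6 -1.10), 6 were lower at 24 weeks and by limma 0 at 8 weeks. Their mean per pool was 0.22 to 0.42 in wild type, 0.22 to 0.37 at 8 weeks, -0.15 to 0.04 at 16 weeks and -0.11 to -0.03 at 24 weeks.

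Cd68, a widely used marker of macrophages, moved little while other macrophage genes rose, and was chosen after its values were seen. It differed by 0.06 ± 0.07 at 16 weeks against wild type (adjusted p = 0.766) and by 0.29 ± 0.07 at 24 weeks (adjusted p = 0.0171), where Adgre1, another such marker, was 3.96 ± 0.27 higher. No explanation of this was tested.

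Genes near Apoe differed between the genotypes at every diet time. Of the 200 tested genes nearest to Apoe, 100 on each side, 8% passed in the same direction at all 3 times, against 1.80% of 19418 other placed genes (Fisher's exact test, p = 1.13e-06), which a segment of chromosome carried over from the strain in which Apoe was targeted could give. A response that grows with the lesions as far as elsewhere is argued against as the cause for the whole set of 16 genes. The median size of their change from 8 to 24 weeks was 0.188, against 0.663 for such genes elsewhere (permutation p = 0.0076, one-sided). These sizes were not scaled to a gene's difference from wild type, so the test cannot exclude growth in proportion to a small difference. A growing response also stays open for the 7 of the 16 genes that differed between 24 and 8 weeks (Bcam, Bcl3, Kcnn4, Slc8a2, Slc1a5, Ccdc61 and Calm3). For sequence variants under single probes, the tolerance of 1 between probes, which 3 of 4 genes met, decides nothing, since these genes changed by about that much or less. With each probe fitted alone, such variants are argued against for Gng8, Calm3 and Zfp296, whose least changed probe still moved by -0.48 ± 0.11, 0.76 ± 0.09 and -0.57 ± 0.14, and stay open for Kcnn4 (0.003 ± 0.166) and the 12 genes with 1 probe.

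Smooth muscle genes were lower and leukocyte genes higher at 16 weeks. Dilution of the vessel wall's RNA by leukocyte RNA alone would lower all wall cell types alike, and is argued against by the endothelial list, whose mean moved 0.807 ± 0.125 above that of the smooth muscle list, and by the fibroblast list, which moved 0.511 ± 0.176 above it. At 8 weeks against wild type the endothelial list also parted from the smooth muscle list (0.644 ± 0.125), but the fibroblast list did not (0.035 ± 0.176). The endothelial list, with group means of -0.38 in wild type and 0.10, 0.03 and -0.03 at 8, 16 and 24 weeks, ran close to the white adipocyte list (-0.42, 0.13, 0.04 and -0.08), and the erythroid list was also lowest in wild type (-0.86 against 0.04, -0.11 and -0.03). More fat or blood in the Apoe-/- pools, which would bring endothelial cells not of the wall, a change in the smooth muscle cells themselves, in the number of endothelial cells, or dilution together with any of these may account for the pattern, and none of them was tested.

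For the Hox genes, the comparison of 16 weeks with wild type does not tell against the same dilution, since their fall matched that of the smooth muscle list there (difference 0.006 ± 0.084). Their later course argues against dilution alone as the cause of both falls. From 16 to 24 weeks their mean moved by 0.340 ± 0.084 relative to the smooth muscle list, which fell again while the Hox mean changed by only 0.02 ± 0.07. This difference cannot decide whether the Hox genes by themselves were diluted, since a change in the smooth muscle cells would also give it. A shorter length of descending aorta in the pools of 16 weeks could lower the Hox mean by the measured -0.399 ± 0.068, but no independent marker of position was fixed, so this cannot be told apart from a change in the cells.

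Other groupings of the pools were tried for each count. For the mean of the Apoe-/- groups against wild type, chance is argued against by a share under 0.05. The real grouping gave 2927 genes and the others at most 612 (1 of 100 splits drawn from 220, the real one, gave as many). The same holds for the F test, with 3615 genes against at most 1997 (1 of 100 splits drawn from 280). Splits not drawn were not counted, and splits that mix the groups add group differences to the spread, which lowers their counts. For the comparisons of 3 pools against 3, the 10 splits are too few for a share under 0.05. The real counts and the highest of the others were 1991 and 1 (16 weeks against wild type), 492 and 0 (8 weeks against wild type), 4504 and 0 (24 weeks against wild type), 472 and 0 (16 against 8 weeks), 1172 and 0 (24 against 16 weeks) and 5676 and 0 (24 against 8 weeks).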
